A study of Arabidopsis thaliana with 8 samples.

How the data were processed

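Biotin-labelled RNA from shoots above the medium was hybridised to the Arabidopsis ATH1 array, per the labels. The 8 groups cross EBR or ethanol with 4 stages, and each has 1 deposited sample that stands for 3 biological replicate arrays per the labels. The submitters' processing notes name MAS5 and GCRMA, without a version or a role, and how the replicate arrays were combined is not given in the sources used here.

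The series' deposited value table holds a linear ratio for each probe set and sample. Its control columns lie at or below 1, with medians of 0.998 to 0.999 and no value above 1, and its EBR columns have medians of 0.968 to 0.991. The deposited ratio was therefore read as relative to the same stage's control, which is an inference from the values. Of the ways to obtain control values that never exceed 1, a geometric mean over the arithmetic mean of the 3 control arrays was taken, and an approximate SD of the log2 control signal was computed from it, which is an inference too. In the authors' deposited tables the excess of the mean signal over the mean log signal (control minus EBR) went with the shortfall of the control columns from 1, with Spearman correlations across probe sets of 0.30, 0.25 and 0.38 at 0 h, 1 h and 3 h. The median SD so read was 0.096, 0.099, 0.107 and 0.101 at the 4 stages in order, and these SDs are approximate and cover control arrays only. For the counts at each stage, the standard error of a log2 ratio was set from these SDs pooled over the 4 stages. For recovery against the other stages it was set from the SD of each stage by itself. In both, EBR arrays were assumed to vary like the control arrays.

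The authors' deposited comparison tables hold linear fold values, mean signal intensity and normalized log2 values per condition. Per the file headers, the listed probe sets passed a 2-way analysis of variance with a corrected p for treatment of 0.05 or less and a fold threshold of 2. The authors' fold tables compare EBR with control at 0 h, 1 h and 3 h, and a further authors' deposited table sets the other conditions against the 0 h control. Their log2 values and intensity are means over arrays made by the authors, with no error, no p-value column and no recovery stage. The direction in the same-stage tables was turned to EBR minus control. The listed fold and the difference of the deposited log2 columns were checked to be equal.

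The groups, the gene lists, the rule for named genes and the alternatives first listed were chosen before the data were examined. That design assumed log2 levels per sample, a floor on low signals and gene lists compared with random lists of like level. The deposited ratios hold no levels, so the floor, the random lists and heat changes over the whole array were not possible. In their place the log2 of EBR over control was taken at each stage, and probe sets at least 2-fold apart were counted. A limma test of the 4 stage ratios against 0, with moderated variances and Benjamini-Hochberg adjustment at 0.05, was added after the data were examined, as were limma contrasts of 1 stage against the rest and of heat against 0 h. The stages share no arrays but may share plant batches, which the labels do not give. On simulated data in the size of the value table (22746 probe sets), the 4-stage test called 56.1% of changes of log2 0.5, 94% of changes of 1 and 100% of changes of 2, and 0.0179% of unchanged probe sets. The simulated noise was independent between stages, so these rates do not cover an offset that the stages share, as from plant batches. Only 66, 67 and 67 changes of these sizes were simulated, while the test called 2495 probe sets in the data. Benjamini-Hochberg adjustment is looser when more probe sets change, so the rates in the data may differ and the share of false calls may be higher. The recovery contrast called 80.5% of simulated changes of log2 2 at recovery alone. The contrast of heat at 1 h and 3 h against 0 h called none of 100 simulated differences of log2 1 and none of 100 of log2 2.

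Genes were named from the locus column of the authors' deposited tables, where 692 of 733 probe sets had 1 locus, and all 692 matched the TAIR10.1 reference table used for symbols. The files name no genome build, so no coordinates are given. A probe set outside these tables is not named here, and 229 of the 535 probe sets that were 2-fold apart at any stage lie in them. The 11 array control probe sets were left out of the tests, and their 3' to 5' ratios were used as a sign of RNA quality. The named genes are, by the fixed rule, the 8 largest named increases and decreases of each same-stage comparison, of heat in the control arm and of the authors' deposited tables, 5 each way for the difference of heat effects, and up to 4 members of each of 25 lists. Genes named for the recovery contrast or for a Gene Ontology term beyond that rule were chosen after their values were seen. Close relatives such as LTP3 and LTP4, or the neighbouring glutaredoxin genes AT4G15660 and AT4G15680, can share signal on an array, so their separate values are uncertain. The ribosomal protein list holds the 48 genes whose synonyms in the reference table carry that wording, so it misses ribosomal genes without it.

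Alternatives were median centring, quantile normalization, a 3-fold threshold and leaving out probe sets with shared sequence. Leaving out each stage, the authors' deposited folds as the source, the probe sets with less control spread, and for heat-raised probe sets a choice by both arms and the value table were added later. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.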

Results

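Shoot transcript levels were measured in seedlings of the Columbia ecotype of Arabidopsis that had grown for 21 days with or without a synthetic brassinosteroid. The steroid was 24-epibrassinolide (EBR), a plant growth hormone analogue given at 1 µM in the medium, and control seedlings had 0.01% ethanol in its place. Shoots were collected at 4 stages, which were before stress (0 h), after heat at 43°C lasting 1 h or 3 h, and after 6 h at 22°C that followed the longer heat. The 2 arms and 4 stages make 8 groups with 1 deposited sample each, and per the labels each sample stands for 3 biological replicate arrays, with at least 30 seedlings pooled per treatment. The value table covers 22746 probe sets of the ATH1 array and holds linear ratios to the control of the same stage. It therefore gives the EBR effect at each stage, but no signal level and no link between stages. A change with heat could be read only from the authors' deposited table against the unstressed control, which lists 708 probe sets. Genes could be named for 692 probe sets, all from the authors' deposited tables, which hold probe sets selected on these samples for an EBR effect, so the direction of any group of named genes is not independent evidence. No single stage has a replicate value in the table, so a ratio at 1 stage carries no p-value on its own. The number of arrays limits the precision.

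The first question was how prolonged EBR altered unstressed shoots. Named genes with high log2 EBR to control ratios at 0 h were the lipid transfer protein genes LTP4 (AT5G59310) at 4.07, LTP3 (AT5G59320) at 3.57 and LTP2 (AT2G38530) at 2.84. The late embryogenesis abundant family gene AT3G02480 had a ratio of 3.40, the lectin family gene AT1G52000 had 3.01, and the wall-associated kinase gene WAK1 (AT1G21250) had 2.96. WRKY70 (AT3G56400), a transcription factor of salicylate-related defence, lay at 2.41. At the other end were the glutaredoxin family genes AT4G15680 at -1.84, AT3G62950 at -1.72 and AT1G06830 at -1.65. The expansin gene EXPA1 (AT1G69530), whose product loosens cell walls, lay at -1.40, and the cytokinin response regulator gene ARR7 (AT1G19050) at -1.34. In all, 216 probe sets were at least 2-fold higher and 28 at least 2-fold lower with EBR. With the control columns read as a measure of spread between the 3 control arrays, 186 of these 244 exceeded 3 standard errors of the difference, pooled over the stages. These 244 had been chosen as at least 2-fold apart, and the median control SD at 0 h was only 0.096. Most would therefore pass by that choice, so this count is not independent evidence. The share among all probe sets was not computed at this stage.

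The next question was whether EBR and control shoots also differed during heat. After 1 h at 43°C the log2 ratio was 3.93 for LTP3, 3.63 for LTP4 and 3.04 for WAK1, and the osmotin gene OSM34 (AT4G11650) had 2.57. After 3 h these ratios were 3.33 for LTP3, 3.20 for LTP4, 2.94 for WAK1 and 2.66 for OSM34, and EARLI1 (AT4G12480), a lipid transfer family gene, lay at 2.89. AT3G62950 was at -1.88 after 1 h and at -1.73 after 3 h. MSRB6 (AT4G04840), which encodes a methionine sulfoxide reductase, was at -1.62 and -1.43. The epidermal transcription factor gene MYB16 (AT5G15310) was at -1.28 after 1 h, and PRIN2 (AT1G10522), a gene of plastid transcription, at -1.23 after 3 h. Counts past 2-fold were 154 higher and 28 lower after 1 h, and 186 higher and 35 lower after 3 h. At 1 h the 3' to 5' signal of the actin and GAPDH control probe sets, a sign of RNA quality, was higher in EBR for all 4 pairs, by a log2 of 0.29 to 0.57.

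**Figure D1:**
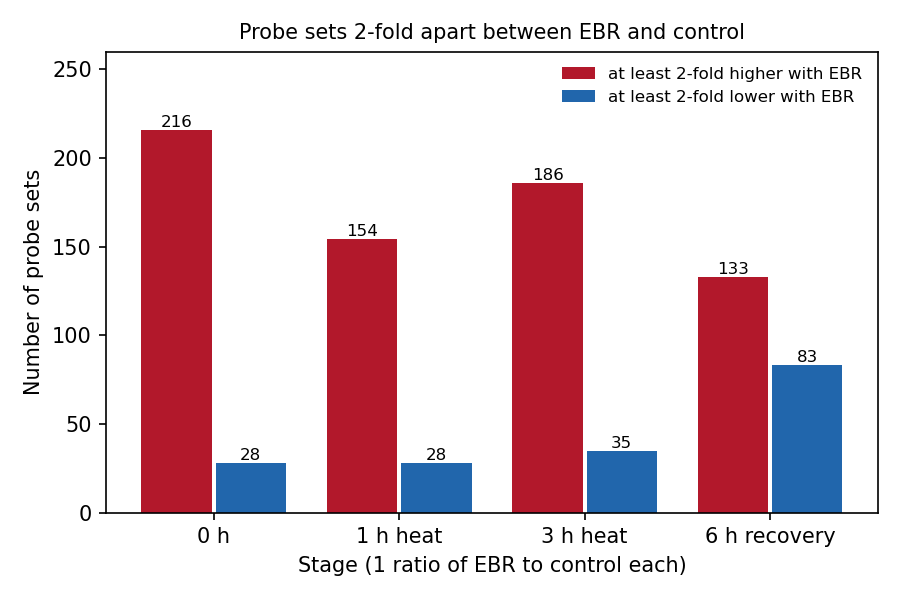
Number of probe sets (vertical axis) at least 2-fold higher (red) or lower (blue) with EBR at each stage (horizontal axis), with 1 ratio per stage and no replicate error. Higher probe sets number 216, 154, 186 and 133, and lower ones 28, 28, 35 and 83.

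At 6 h of recovery LTP3 still had a log2 ratio of 3.16, LTP4 2.97 and WAK1 2.94. ELI3-2 (AT4G37990), a pathogen-induced alcohol dehydrogenase gene, lay at 1.82, with control arrays that differed by an SD of 1.37, and the calmodulin-like gene AT2G41090 at 1.75. The lowest named ratios were those of AT3G62950 at -2.28, MSRB6 at -1.83 and the glutaredoxin family genes AT1G06830 at -1.55 and AT4G15660 at -1.38. At this stage 133 probe sets were at least 2-fold higher and 83 lower with EBR, a split of 61.6% higher. Quantile normalization, which by construction gives the same split of 164 to 40 at every stage, put 80.4% higher. At recovery the 3' to 5' signal of the actin and GAPDH control probe sets was lower in EBR for all 4 pairs, by log2 values of -0.47, -0.14, -0.16 and -0.08.

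Over the 4 stages together, the question was which genes EBR shifted whatever the temperature. LTP4 rose by a mean log2 ratio of 3.47 ± 0.49 (SD, n = 4 stages; limma adjusted p = 0.000171) and WAK1 by 2.97 ± 0.05 (limma adjusted p = 1.52e-06). AT2G41090 rose by 2.11 ± 0.26, the pyrimidine breakdown gene PYD4 (AT3G08860) by 2.03 ± 0.45 and the defence-related LURP1 (AT2G14560) by 1.67 ± 0.38, with limma adjusted p-values of 0.000171, 0.00134 and 0.00143 in that order. AT3G62950 fell by 1.90 ± 0.26 and AT1G06830 by 1.47 ± 0.17 (limma adjusted p = 0.000298 for both), and MYB16 fell by 0.95 ± 0.35 (limma adjusted p = 0.00583). All of these genes had the same sign at 4 of 4 stages. The limma test on the 4 stage ratios called 1151 probe sets that rose and 1344 that fell, with a mean of at least 2-fold in 114 and 18. Of all probe sets, 24 were at least 2-fold higher and 6 at least 2-fold lower at every stage, and 95 were higher at both 0 h and 1 h, against 1.46 by chance. With each stage centred on its median, 1313 rose and 960 fell, which turned the share that rose from 46.1% to 57.8%. Leaving out the 1 h ratio left 262 and 186 calls, leaving out 0 h left 438 and 349, and leaving out 3 h left 429 and 403. These p-values measure agreement between stages, which is not the spread between seedling batches within a stage.

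**Figure D2:**
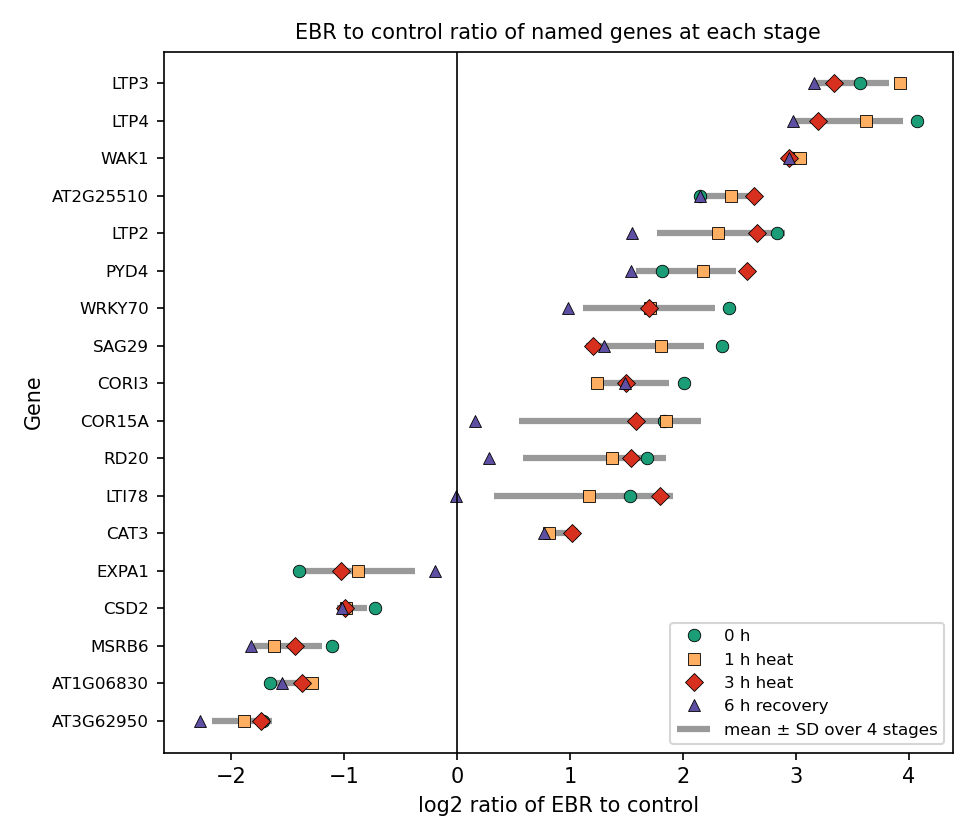
The log2 ratio of EBR to control (horizontal axis) of 18 named genes (vertical axis), with 1 symbol per stage and a grey bar for the mean ± SD over the 4 stages. WAK1 lies between 2.94 and 3.04 at every stage, while LTI78 lies at -0.01 at recovery and between 1.17 and 1.80 at the other stages.

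Among the fixed gene lists, abscisic acid and dehydration genes had the most named members, 6 of 27. Of these 4 rose, none fell and 2 were not called by limma. Adjusted over these 6 named members alone, all 6 rose. Here and below, adjustment over a list covers only its named members. These had already been selected for an EBR effect, so it adds no independent evidence. COR15A (AT2G42540), a chloroplast cold-protection protein gene, rose by a mean log2 of 1.36 ± 0.81 (SD, n = 4 stages; limma adjusted p = 0.0185). RD20 (AT2G33380), which encodes a lipid droplet caleosin, rose by 1.22 ± 0.63, and LTI78 (AT5G52310), the desiccation gene also called RD29A, by 1.12 ± 0.80, with limma adjusted p-values of 0.0125 and 0.0325. The dehydrin gene ERD10 (AT1G20450) had a mean of 0.70 ± 0.56 (limma adjusted p = 0.0513). The calls of COR15A, RD20 and LTI78 were lost when the 0 h, the 1 h or the 3 h ratio was left out. The list's share of genes in the authors' deposited tables was above that of the other lists by Fisher's exact test (two-sided p = 0.005), but not after adjustment over 25 lists (adjusted p = 0.125).

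The few named members of the jasmonate, salicylate and senescence lists rose, but the share of these lists in the authors' deposited tables did not differ from that of other lists (Fisher's exact test, adjusted p = 0.933, 0.933 and 0.868). Of 24 jasmonate genes 2 were named and both rose, LOX2 (AT3G45140), a lipoxygenase gene of jasmonate synthesis, by a mean log2 of 1.13 ± 0.33 and CORI3 (AT4G23600) by 1.56 ± 0.32 (SD, n = 4 stages). Of 20 salicylate genes both named members rose, WRKY70 by 1.70 ± 0.58 and CBP60G (AT5G26920) by 0.48 ± 0.32. Both named members of the 14 senescence genes rose, the sugar transporter gene SAG29 (AT5G13170) by 1.66 ± 0.52 and SAG13 (AT2G29350) by 0.93 ± 0.30. The anthocyanin regulator PAP1 (AT1G56650) and the glutathione transferase gene TT19 (AT5G17220, GSTF12) were the 2 named of 16 flavonoid genes and rose by 0.57 ± 0.38 and 0.93 ± 0.49. Their control signals at 0 h in the authors' deposited table were low, 4.85 and 4.54, where the lowest listed signal was 3.55. There the log2 ratios at 0 h, 1 h and 3 h were 1.89, 0.19 and 0.03 for PAP1. For TT19 they were 1.18, 0.62 and 0.40. Without a background level the rises of PAP1 and TT19 are uncertain. MAM3 (AT5G23020, IMS2), a gene of methionine chain elongation and the 1 named of 17 glucosinolate genes, rose by 0.91 ± 0.58. The limma adjusted p-values of these 9 genes lay between 0.00134 and 0.0384. Adjusted over the few named members of each list alone, all 9 rose. The calls of CBP60G and MAM3 were lost without any 1 of the 0 h, 1 h and 3 h ratios, and those of PAP1 and TT19 without 0 h or 1 h.

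Among antioxidant, brassinosteroid and cell wall genes, calls went both ways. The catalase gene CAT3 (AT1G20620) rose by 0.91 ± 0.13 and the chloroplast superoxide dismutase gene CSD2 (AT2G28190) fell by 0.93 ± 0.13 (limma adjusted p = 0.00143 for both), the 2 named of 23 antioxidant genes. Of 21 genes of brassinosteroid inactivation and signalling, BEE2 (AT4G36540), an early brassinosteroid-induced factor, fell by 0.77 ± 0.07 and BRH1 (AT3G61460), a brassinosteroid-responsive RING finger gene, rose by 0.37 ± 0.21. BAS1 (AT2G26710), whose enzyme inactivates brassinosteroids, had a mean of 0.29 ± 0.39 (limma adjusted p = 0.234) with 0.87 at 0 h. Of 25 cell wall and growth genes, EXPA1 fell by 0.87 ± 0.50, EXPA11 (AT1G20190) rose by 0.35 ± 0.18 and SAUR9 (AT4G36110) was not called. Adjusted over the 3 named members of the list alone, SAUR9 was called too, with 2 that rose and 1 that fell. The floral organ gene PI (AT5G20240) was the 1 named of 12 floral markers and fell by 0.75 ± 0.12.

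None of the 3 named chaperone genes was called across the stages. Both named members of 12 HSP70 genes were not called, with means of 0.26 ± 0.30 for Hsp70-2 (AT5G02490) and -0.28 ± 0.55 for the mitochondrial mtHsc70-1 (AT4G37910). Hsp70-2 lay at 0.43, 0.40 and 0.41 at 0 h, 1 h and 3 h, but at -0.18 at recovery. For mtHsc70-1 these ratios were -0.69, -0.52 and -0.44, and 0.53 at recovery. The missing calls over the 4 stages therefore do not show equal levels at each stage. The co-chaperone J2 (AT5G22060) had 0.08 ± 0.31. Of 25 heat shock factors and related regulators, HSFA4A (AT4G18880) rose by 0.55 ± 0.15 (limma adjusted p = 0.00659), and HSF4 (AT4G36990, also called HSFB1) had a mean of 0.33 ± 0.49 and was not called. The auxin gene WES1 (AT4G27260, GH3.5) had 0.31 ± 0.30 and was not called, except when adjusted over its list alone (adjusted p = 0.0223). No member could be named in 11 lists. These were the small heat shock proteins, endoplasmic reticulum folding, brassinosteroid synthesis, ethylene, photosynthesis and cell cycle. The others were aquaporins, circadian clock, root markers, reference genes and cytosolic ribosomal proteins. None of their members was listed under 1 locus in the authors' deposited tables, and the size of their EBR effect is not known here. The calls of EXPA1, EXPA11 and BRH1 were lost without any 1 of the 0 h, 1 h and 3 h ratios, and that of HSFA4A without 1 h.

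Gene Ontology terms in the authors' deposited tables were compared for direction among the 692 named genes. All 12 genes of the response to abscisic acid had a mean above 0 and 11 rose (two-sided Fisher's exact test, adjusted p = 0.028), and 15 of 16 genes of the response to cold were above 0 and 12 rose (adjusted p = 0.0407). The first group holds LTP3, LTP4, CORI3, LTI78 and RD20, so it overlaps the lists above. Of 17 calcium-binding genes 16 were above 0 and 14 rose (adjusted p = 0.028), among them WAK1 and AT2G41090. Genes below 0 gathered in translation, with 12 of 13 below and 11 that fell (adjusted p = 0.000805), and in chloroplast, with 49 of 83 below and 36 that fell (adjusted p = 0.000805), though 34 were above 0 and 27 rose. All 10 genes of embryo development were below 0 and 6 fell (adjusted p = 0.000805). Cell redox homeostasis had 9 of 11 below 0 and 8 that fell (adjusted p = 0.0237), and this group holds the glutaredoxin family genes AT3G62950, AT1G06830, AT4G15680, AT4G15660 and AT2G30540. The comparison covered 58 terms with at least 10 named genes and was chosen after the data were examined. For the 11 terms that passed, the counts above 0 were equal under median centring and quantile normalization. The stage medians lay between -0.042 and -0.008, so centring could hardly have changed these counts. The defence response (adjusted p = 0.269) and the response to jasmonic acid (adjusted p = 0.361) did not pass.

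Whether the EBR effect differed by stage was tested as recovery against the other 3 stages. Recovery enters this limma contrast with 1 ratio and no replicate error, so the error comes from the other 3 stages and recovery is assumed to vary like them. Of the 6 named dehydration genes, 3 passed this test and were closer to control at recovery, where the log2 ratio was 0.16 for COR15A, -0.01 for LTI78 and 0.28 for RD20, against at least 1.17 for each of them at every other stage. The difference was -1.59 for COR15A, -1.50 for LTI78 and -1.24 for RD20, with limma adjusted p-values of 0.0273, 0.0452 and 0.0401. COR47, ERD10 and ERD14 did not pass (limma adjusted p = 0.385, 0.281 and 0.125). At recovery COR47, ERD10 and ERD14 nevertheless also lay near control, with log2 ratios of 0.03, 0.08 and 0.06. Their ratios were 1.12, 1.43 and 1.03 at 0 h, and 0.26, 0.54 and 0.67 after 1 h. AT3G02480 differed by -2.69 and HSF4 by -0.98, while ELI3-2 differed by 1.29 and mtHsc70-1 by 1.08. The control SD at recovery was 0.81 for RD20 and 1.37 for ELI3-2, so their differences lay only 1.76 and 1.15 standard errors from 0 by that spread and are uncertain. For COR15A the control SD was 0.24 at recovery but 0.62 pooled over the stages. Its distance from 0 in standard errors therefore depends on which SD is used. In all 85 probe sets had a higher and 25 a lower ratio at recovery, and 16 of these could be named. With each stage centred on its median, which shifts every difference by 0.00535, 25 and 8 were called, because adjusted p-values near 0.05 crossed it (at most 0.0603). After quantile normalization the median size of these 110 differences was 1.14 against 1.096. The main calls that were lost all had a lower ratio at recovery, the side on which the dehydration genes lie. Control arrays of the 110 had a median SD of 0.34 at recovery against 0.15 at other stages, and the 3' to 5' signal of the control probe sets was lower in EBR at recovery as given above. The same test of 0 h, 1 h or 3 h against the rest called no probe set by limma. There the recovery ratio is among the rest and adds to the error. Its Pearson's r with the other stages across probe sets was 0.39 to 0.41, against 0.61 to 0.65 among those stages. No changes were simulated for these contrasts, so they do not show that recovery alone differed.

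The change with heat itself was read from the authors' deposited table, which holds condition means and no error. In control shoots HSF4, a heat shock factor gene, was higher by a log2 of 8.10 after 1 h and 8.29 after 3 h in the authors' deposited table. The galactinol synthase genes GolS1 (AT2G47180) and GolS2 (AT1G56600), whose products start raffinose synthesis, were higher by 6.72 and 5.75 after 1 h in that authors' deposited table, and the lipid droplet protein gene AT1G67360 by 7.40. Hsp70-2 was higher by 5.40. The control signal at 0 h was low, 8.95 for GolS2, 13 for Hsp70-2 and 14.9 for HSF4 in the authors' deposited table, and without a background level these changes are approximate. EXPA1 had the lowest value, -3.73 after 1 h, followed by AT1G33600 at -3.04 and BRH1 at -2.97 in the authors' deposited table. Of the 708 listed probe sets, 80 were at least 2-fold higher and 145 lower after 1 h in control shoots, and 72 and 158 after 3 h. In EBR shoots the authors' deposited table gave 78 higher and 172 lower after 1 h, and 106 and 191 after 3 h. Quantile normalization over the listed probe sets gave 83 and 106 for control at 3 h, 107 and 106 for EBR at 1 h, and 135 and 125 for EBR at 3 h. By construction it gives every condition the same distribution, which tends to draw the higher and lower counts together. The 708 probe sets had also been selected for an EBR effect. Neither set of counts therefore gives the direction of the heat response over the array.

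The design also asks whether EBR altered the response to heat. In the authors' deposited table the changes of the 2 arms were correlated across probe sets, which are not independent replicates, with Pearson's r of 0.92 after 1 h (slope of EBR on control 0.93) and 0.91 after 3 h (slope 0.99). Of the 80 probe sets 2-fold higher after 1 h in control shoots, 60 had a smaller change in EBR shoots, with a median difference of -0.34. For HSF4 the change in the authors' deposited table was 6.89 with EBR against 8.10 without, from signals at 0 h of 39.2 and 14.9, but in the value table its difference was only -0.08. For the 80 probe sets the median difference in the value table was -0.07. Chosen by the change in EBR shoots instead, the median difference after 1 h in the authors' deposited table was 0.09. Chosen by the mean of both arms, it was -0.14 after 1 h and 0.14 after 3 h in that authors' deposited table. In the value table the choice by both arms gave -0.01 after 1 h and 0.15 after 3 h. The metal-transport family gene AT5G52760 had a heat value of 3.32 with EBR against 0.40 without in the authors' deposited table, where its mean signal after 1 h was 92.8 and a low 10.1.

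**Figure D3:**
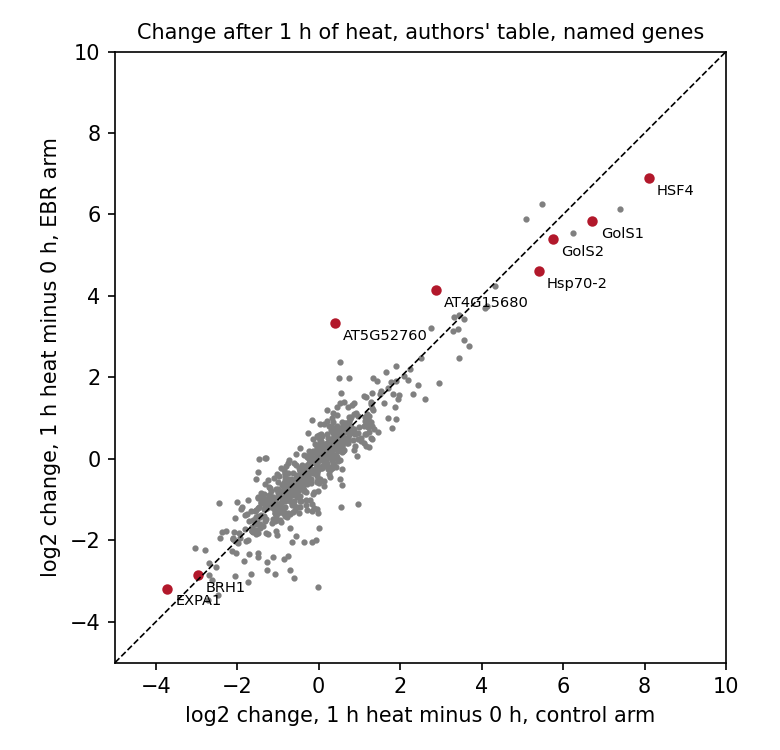
Log2 change from 0 h to 1 h of heat in control (horizontal axis) and EBR shoots (vertical axis) in the authors' deposited table, 1 point for each of 671 named genes, with the dashed line at equal change. AT5G52760 lies at 0.40 and 3.32, and HSF4 at 8.10 and 6.89, a gap that the value table does not show (-0.08).

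In the value table the difference of heat effects is the ratio at a stage less that at 0 h. It was 1.91 for AT5G52760 and 1.23 for PCC1 (AT3G22231), a pathogen-responsive gene, after 1 h, and -1.69 for the growth-related SAUR9. After 3 h EARLI1 had the highest named value, 2.16, and AT2G37870, a lipid transfer family gene, the lowest, -1.67. At recovery ELI3-2 had 1.52 and AT3G02480 had -3.13. Probe sets with a difference of at least 2-fold numbered 18 more and 49 less after 1 h, 40 and 42 after 3 h, and 95 and 163 at recovery, which became 131 and 106 with quantile normalization. Heat at 1 h and 3 h together against 0 h, where 0 h is 1 ratio, called none by limma. The same contrast called none of 100 simulated differences of log2 2, so it could not have shown a difference of this size and does not argue against one.

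The authors' deposited same-stage tables, selected by an analysis of variance for treatment at a corrected p of 0.05 and a 2-fold threshold per the file headers, gave larger values for most listed probe sets, 267 of 273 at 0 h, 226 of 239 after 1 h and 241 of 256 after 3 h. LTP3 was an exception, with 3.21 at 0 h in the authors' deposited table against 3.57. WAK1 had a log2 of 4.51 at 0 h in the authors' deposited table, against 2.96 in the value table, and AT1G06830 had -2.98 against -1.65. PCC1 led the authors' deposited table at 3 h with 4.26. The authors' deposited tables list 214 higher and 59 lower at 0 h, 184 and 55 after 1 h, and 198 and 58 after 3 h, with 142 probe sets in all 3 tables. Since the p for treatment was required in each table, their overlap has no chance value to compare with. Every listed probe set had the same sign in the value table, with Pearson's r across probe sets of 0.94 to 0.95, and 46.9% to 48% of them reached 2-fold there.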

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

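The test of recovery against the other stages and the tests of standard errors and of the size of the differences in this part were chosen after the result was seen. The difference between stages stood out by a limma contrast, in which 110 probe sets passed for an EBR to control ratio at recovery apart from that at the other 3 stages, with recovery as 1 ratio without replicate error and assumed to vary like the others. Among the named genes the log2 difference was -2.69 for AT3G02480, -1.59 for COR15A, -1.50 for LTI78, -1.49 for the protease inhibitor gene KTI1, -1.24 for RD20, -1.18 for BGLU18, whose enzyme releases abscisic acid from its glucose ester, -1.10 for the phospholipase gene PLA2A, -1.07 for AHP4 and -0.98 for HSF4. It was 0.90 for EMB3131, 1.00 for AT1G08610, 1.03 for AT2G18330, 1.04 for AT2G17670, 1.05 for AT5G61350, 1.08 for mtHsc70-1 and 1.29 for ELI3-2.

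Whether scaling between samples lies behind these differences was not settled. The main calls lost after quantile normalization all had a lower ratio at recovery, the side on which the dehydration genes lie. That scaling keeps the order of probe sets within a stage, so it tests the size of the largest differences only weakly. It moved single differences by up to 0.66, and their median size was 1.14 against 1.096. The counts alone, 122 after it and 33 after median centring, do not decide, since centring shifted every difference by the same 0.00535 and ended calls near the threshold (highest adjusted p 0.0603). Spread between the control arrays may account for part of the calls, because 41 of the 110 differences lay within 3 standard errors by that spread and 69 beyond, against 17% of all probe sets beyond. For all 110 together spread and stage cannot be told apart, and a new test on the probe sets with the smaller spread called 4, but these hold only 13 of the 110 and none of the 16 named genes (for RD20, BGLU18, PLA2A and ELI3-2 the difference lay within 3 standard errors). A return of some dehydration genes to the control level after heat is a biological explanation the design offers, and it stays open as untested. The same-stage ratios cannot tell a fall in EBR shoots from a rise in control shoots at recovery.

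Array control probe sets, which the gene comparisons do not use, gave a higher 3' to 5' signal with EBR than in control at 1 h of heat. The log2 difference was 0.47 and 0.57 for the 2 actin pairs and 0.40 and 0.29 for the 2 GAPDH pairs, and it was not tested. At recovery all 4 differences were below 0, at -0.47 and -0.16 for actin and -0.14 and -0.08 for GAPDH, and what RNA quality does to the recovery differences was not tested.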

How the results depend on the processing

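The listed folds, the left-out stages, the limma tests and the spread subset were chosen after the data were examined. No paired analysis was possible because replicate numbers pair nothing in groups of 1 sample, apart from the 4-stage test, which takes EBR against control within stages, and no single replicate array could be left out. Alternatives with a floor on signal, random lists of like level and a corrected p of 0.01 were not run, since the value table holds ratios and the tables list no p-value, and heat at recovery against 0 h was not analysed here. The value table has no signal over background. Leaving out _s_at and _x_at probe sets (1061) moved no count by over 1.5 times, and no named gene reversed.

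With a 3-fold threshold, which by construction passes fewer, EBR counts at 0 h, 1 h, 3 h and recovery were 48, 38, 48 and 13 higher and 9, 3, 5 and 9 lower. Differences of heat effects were then 1, 4 and 10 at least 3-fold more and 6, 4 and 16 less at 1 h, 3 h and recovery. Heat gave 43 higher and 51 lower at 1 h and 43 and 71 at 3 h in control, and 46 and 71, then 53 and 93, with EBR. The authors' deposited tables kept 104, 79 and 79 higher and 7, 7 and 9 lower at 3-fold. The authors' deposited folds gave 59, 55 and 58 lower in place of 28, 28 and 35. Quantile normalization gave 40 lower in EBR at recovery, a count it makes equal at all stages by construction, and 106 probe sets with a heat difference at least 2-fold less there, and for heat with EBR it gave 106 lower at 1 h and 125 at 3 h. For the other moves the cause was not tested.

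Leaving out 1 stage moved the 4-stage calls between 262 and 1648 that rose and between 186 and 1636 that fell, the highest without recovery, of which 1053 and 1131 were shared with the main calls. Of 100 named genes, 77 were called, and 24, 38 and 22 calls were lost without 0 h, 1 h and 3 h, and none without recovery, where 15 were gained (1 without 0 h). The recovery contrast gave 25 higher and 8 lower after median centring, which shifted every difference alike, 16 lower after quantile normalization, and 1 higher and 3 lower among probe sets with the smaller control spread. The median log2 of the list of brassinosteroid inactivation and signalling ranged from 0.093 without 0 h to 0.361 without 1 h, against 0.29. All other list medians moved by less than their spread between stages in these settings.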

Other observations

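The tests of the swapped arms, of the listed folds, of the level before stress and of the heat-raised probe sets by both arms and in the value table were chosen after the result was seen. No named gene was in the fixed ribosomal list as matched here. Outside it, 9 named genes carry the Gene Ontology term for a structural constituent of the ribosome. They were looked up after the data were examined. Of the 9, 8 fell with EBR over the 4 stages by the limma test, among them AT2G37600 by a mean log2 of 0.67 ± 0.19 (SD, n = 4 stages) and AT3G06680 by 0.61 ± 0.07. AT2G40010 fell by 0.59 ± 0.18 and AT3G05560 by 0.48 ± 0.13. The 1 gene that rose was RPS2, by 0.99 ± 0.21, which is known as a disease resistance gene and shares its symbol with a ribosomal protein. These 9 genes are among the 13 of the translation group. All 9 were in the authors' deposited tables and so had been selected for an EBR effect.

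Lipid transport held 10 named genes, of which 9 rose and 1 fell with EBR, with a median log2 of 1.19. Its share above 0 did not differ from that of the other named genes after adjustment (adjusted p = 0.232).

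Swapping EBR and control within stages gives 8 distinct patterns. The real pattern called 2495 probe sets and was the 1 pattern of that size, and the highest of the other patterns called 0. With 8 patterns no share under 0.05 can be reached.

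Listed folds exceeded those of the value table by a median log2 of 0.53 at 0 h, 0.46 at 1 h and 0.45 at 3 h. Averaging signals in place of logs does not account for it, since it moved the listed values by a median of at most 0.0583. A different treatment of weak signals by 2 normalizations may account for it, as the gap shrank with signal at every stage (Spearman correlation across probe sets -0.52 to -0.50). That the 2 sources differ in normalization is assumed. The listed probe sets had also been selected for a listed fold of at least 2, which by itself favours larger listed values. The correlation with signal cannot tell these explanations apart, and selection was not tested. No biological explanation was tested, since the listed folds and the value table come from the same samples.

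In the authors' deposited table, probe sets raised by 1 h of heat in control differed in their change with EBR by a median log2 of -0.34 (95% bootstrap interval over probe sets -0.46 to -0.20), but chosen by the EBR arm's change the median was 0.0863 (-0.08 to 0.25). Each of these choices moves the median toward its own arm. Chosen by the mean of both arms, the median was -0.14 (-0.29 to -0.02) at 1 h and 0.14 (0.03 to 0.27) at 3 h. In the value table at 1 h, the probe sets chosen by control had a median of -0.0695 (-0.11 to 0.01). There the choice by the EBR arm gave 0.17 (0.03 to 0.30) and the choice by both arms -0.0061 (-0.07 to 0.15). The value table thus did not show the smaller change that the choice by both arms left in the authors' deposited table. Selection stays open as a cause, and most of the smaller change may belong to the values of the authors' deposited table. The level before stress is another candidate explanation. These values cannot decide it, since the 0 h ratio is itself a term of the difference. In the value table the EBR to control ratio at 0 h had a median of 0.44 (0.33 to 0.54) in the 78 probe sets chosen by the EBR arm. These 78 showed no smaller change. The 0 h ratio was above 0 in 71 of the 78 and in 372 of the 630 other listed probe sets, whose median was 0.31. The authors' deposited table had itself been selected for an EBR effect. The 80 probe sets chosen by control had a median of 0.52 (0.46 to 0.67) at 0 h, with little smaller change in the value table (-0.0695).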
